A study of Mus musculus with 8 samples.

How the data were processed

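Total RNA of mouse pancreas (C57 BL6) was measured 6 days after tamoxifen, given at 3 mg per 40 g of body weight, with 4 arrays of control (WT) and 4 of Lmna knockout (KO) pancreas. Per the labels' protocols, biotin-labelled cDNA was made from 100 ng of RNA with a whole-transcript kit. The authors deposited 1 table of 41345 rows by 8 arrays, and per the submitters' processing notes oligo, RMA and limma were used, with no versions given. RMA corrects background, normalizes between arrays and summarizes probes, and the deposited values fit log2 expression by their range, although the log base is not given in the sources used here. Background levels, probe positions and scan batches are not given in the sources used here, so no array had a batch to test and signal over background is unknown for each gene. Columns were matched to samples by their names, and 0 columns were left unmapped.

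Rows were named through the platform annotation. Of the rows, 23521 (56.9%) had 1 gene symbol, 1814 had several and 16010 had none; the last 2 kinds were left out of the gene tests. Of those with 1 symbol, 23328 had an Entrez identifier found in a RefSeq table of the mouse assembly GRCm38.p6, which changed 0 symbols. For 1082 genes in several rows the row with the highest mean was kept, giving 22180 genes with no filter on dim rows. The build of the array design is not given in the sources used here, so no coordinates are printed.

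Genotype was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 8 arrays with genotype as the only factor, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; changes are log2 differences, KO minus WT, with their standard errors. Before the data were examined, 47 gene lists were fixed, among them 2 for checking sex, and 44 with at least 5 measured members were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Counts of members past the threshold are given over all genes and adjusted over the list alone. The lists were acinar digestive enzymes, acinar transcription factors, markers of ductal, beta, other islet, stellate, endothelial, macrophage, neutrophil, T and NK, B and plasma, mast, adipocyte, mesothelial and Schwann cells, and pathways from cell cycle, DNA damage and protein folding to metabolism. The level of a list in an array is the mean over its genes of the log2 value minus its mean over the 8 arrays, compared by an exact two-sided permutation test. All exact permutation tests here take the arrays as unpaired. If the replicate numbers pair the arrays, the 8 splits that part all 4 pairs are too few for a p under 0.05. The genotype by sex difference was fitted with 4 genotype-by-sex groups.

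The rule for named genes was fixed before the data were examined. It took the 12 largest rises and 12 largest falls among genes past the threshold, with no overlap between groups and a mean of at least 6 in the higher group, leaving out predicted genes, immunoglobulin and T cell receptor segments and small RNAs. It added Lmna, Lmnb1, Lmnb2, Rb1 and Trp53 (the last not analysed here), up to 4 members of smallest p per list, and 5 genes of the sex difference. Of the called list members taken by this rule, the results give values only for ones whose call held in each alternative that tested them but males only, a choice made after seeing the alternatives, so these genes are steadier than the rest of their lists. Alternatives fixed beforehand were sex or the replicate number as a term, males only, each array left out, a second quantile normalization, median centring, a trend with robust eBayes, array weights, filters on level, the mean of a gene's rows, all rows, an ordinary equal-variance test, an estimated correlation and fry; cyclic loess, level-matched lists and the block combined with an estimated correlation were added after seeing the data.

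Both groups carry replicate numbers 1 to 4 in the labels, and replicate 4 is the female in each. Whether these numbers pair the arrays was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. The correlations were 0.26, 0.17, 0.11 and 0.14, all over 0.1, so the numbers were taken to pair the arrays. Of the 12 pairs with different numbers 2 were also over 0.1, WT 4 with KO 2 (0.125) and WT 3 with KO 1 (0.106); the pairing is read from the data and the labels name no shared litter or day. With the replicate number as a block, 5046 genes passed, against 4792 without it.

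The steps were tested on simulated data of 22180 genes with 200 changed genes. They recovered 82% of changes of 1 log2 unit and 97% of those of 2 units at 4 against 4 arrays, 5.79% of the calls were unchanged genes, and with no change there were 0 calls. Of 3 shifted lists, 3 were called. Genes were drawn independently of one another, so the simulation does not show how the list test behaves on correlated genes. Noise took the variance that eBayes gave each gene, equal in both groups, with no pair effect and no shift by level. The real data had 4792 calls and wider spreads in some genes, such as an SD of 1.50 for Fetub in KO. The recovered and false shares therefore need not hold for the real data. For the sex difference, 90% of differences of 3 log2 units were recovered, with 14 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.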

Results

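The data collected were log2 expression values of total RNA from mouse pancreas, measured on 8 whole-transcript arrays 6 days after tamoxifen was given by intraperitoneal injection. Tamoxifen is the drug commonly used to switch on a Cre recombinase, and the series title places the loss of lamin A/C in acinar cells, the enzyme-producing cells of the exocrine pancreas. Lamin A/C, encoded by Lmna, is a filament protein of the inner face of the nuclear envelope. Control pancreas (called WT here, 4 arrays) was compared with Lmna knockout pancreas (KO, 4 arrays), and each genotype held 3 males and 1 female. The number of arrays limits the precision, and the labels name separate samples without saying more on how the animals were chosen, so the p-values measure the spread between these samples. Xist, transcribed from the inactive X chromosome, read 7.70 in the WT female and 7.91 in the KO female and at most 1.89 in the 6 males, so no array went against its sex label.

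The comparison of KO with WT pancreas asks which transcripts differ when Lmna has been deleted, and the targeted gene comes first. Lmna read 2.54, 3.13, 2.67 and 2.88 in WT 1 to WT 4 and 2.33, 2.58, 2.73 and 2.61 in KO 1 to KO 4. The difference was -0.24 ± 0.15 (log2, KO minus WT, ± SE, n = 4 per group, limma adjusted p = 0.264, exact two-sided permutation p = 0.2), smaller than the spread between arrays allows to call. This row of the array was dim, at percentile 52.8 of the mean levels of all genes. It is not known whether its probes lie in the deleted part of the gene, so the Lmna values do not check the genotype labels. Of the other lamins, Lmnb1 rose by 0.88 ± 0.19 (adjusted p = 0.0124), while Lmnb2 differed by -0.44 ± 0.15 (adjusted p = 0.0665) and passed without WT 1 (-0.57) and with array weights (-0.45). Rb1, the retinoblastoma protein that binds lamin A/C, rose by 1.19 ± 0.26 (adjusted p = 0.0138). Among males only, with 3 arrays per genotype, Lmnb1 (0.70) and Rb1 (1.22) lost their call.

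In KO pancreas 12 to 16 genes were higher in each of the PERK, ATF4 and CHOP, chaperone, p53, DNA replication and macrophage lists, and 10 digestive enzymes and 3 acinar transcription factors were lower. Many genes of middle level were higher too: 1025 of 2797 at a mean level of 4 to 5, 758 of 1911 at 5 to 6 and 426 of 1288 at 6 to 8. The 16 of 42 measured genes of the PERK list, whose median level was 5.99, lie near these shares. Camera called the lists named here with its preset correlation and none of the 44 with an estimated one. The rise that led the named genes was that of Ddit3, the transcription factor CHOP of the integrated stress response, at 4.64 ± 0.31 log2 units (24.9-fold, from 3.73 ± 0.61 to 8.37 ± 0.45, SD, n = 4 per group, limma adjusted p = 0.000298). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 3.39 ± 0.26 (adjusted p = 0.000437), and Fgf21, a hormone secreted under metabolic stress, by 2.96 ± 0.41 (adjusted p = 0.00249). The elastase Cela3a showed a change of -3.24 ± 0.24 (adjusted p = 0.000437), chymotrypsin C (Ctrc) of -2.24 ± 0.23 (adjusted p = 0.00111) and pancreatic amylase Amy2b of -1.89 ± 0.14 (adjusted p = 0.000437), all lower in KO.

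The other rises among the 12 named by size were those of the secreted protein fetuin B Fetub (3.71 ± 0.67), the glutathione S-transferase Gstp3 (3.71 ± 0.54), the p53-inducible stress protein Trp53inp1 (2.42 ± 0.39), the interferon-activated gene Ifi204 (2.37 ± 0.29), and the mitochondrial thioesterase Acot2 (2.36 ± 0.32). Also higher were the stearoyl-CoA desaturase Scd1 (2.34 ± 0.60), the macrophage receptor Adgre1 (2.29 ± 0.38), the ubiquitin-activating enzyme Uba6 (2.23 ± 0.32) and the mitochondrial protease Lonp1 (2.22 ± 0.18). Their adjusted p ran from 0.000502 for Lonp1 to 0.0234 for Scd1. The Scd1 value rested in part on KO 2, which read 9.28 against 6.47 to 6.78 in the other KO arrays. Its call was lost without WT 2 (2.28), without WT 3 (2.15), after a second quantile normalization (1.98) and after cyclic loess (1.94). The other falls were those of the p24-family cargo receptor Tmed11 (-3.14 ± 0.46), the pancreatic serine protease inhibitor Serpini2 (-3.10 ± 0.72), the hepcidin-family peptide Hamp2 (-2.70 ± 0.49), and the BMP antagonist Sostdc1 (-2.36 ± 0.43). Also lower were Susd2 (-2.17 ± 0.30), the acute-phase protein Itih4 (-1.97 ± 0.32), the Rap1 GTPase-activating protein Rap1gap (-1.78 ± 0.17), the secreted lectin Reg3a (-1.71 ± 0.31) and the scaffold protein Homer2 (-1.65 ± 0.24). Their adjusted p ran from 0.000889 for Rap1gap to 0.0168 for Serpini2. In each of these genes all 4 KO arrays lay on one side of all 4 WT arrays, which was part of the rule that chose them.

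**Figure D1:**
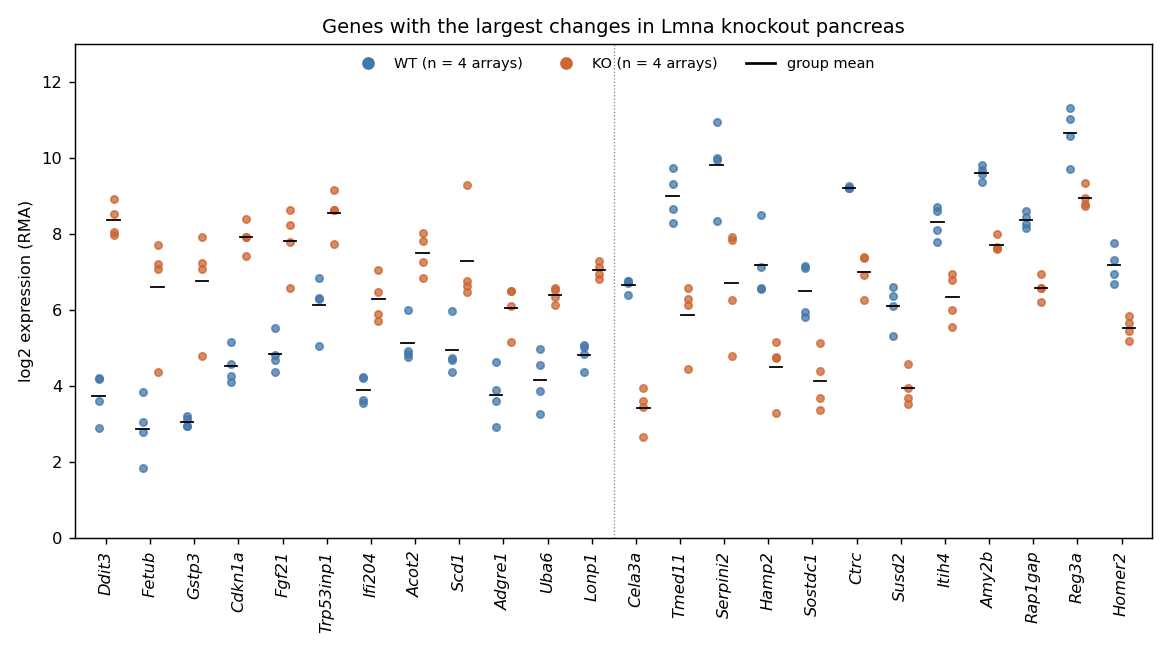
The log2 expression (vertical axis, RMA values) of the 12 named genes with the largest rises and, right of the dotted line, the 12 with the largest falls (horizontal axis), with 1 point per array for 4 WT and 4 KO arrays and a bar at each group mean. The KO and WT points do not overlap in any of them; Ddit3 moved from a mean of 3.73 to 8.37, and Scd1 in KO 2 (9.28) stood apart from the other KO arrays.

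Over all 22180 genes tested, 4792 passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 3241 higher and 1551 lower in KO. A change of at least 1 log2 unit was seen for 1057 of the higher and 116 of the lower genes. The 2 groups did not overlap in 6075 genes (27.4%), against the 2.86% that chance gives. Of the calls, 67.6% were higher in KO. That share was 51.8% after a second quantile normalization (1228 higher, 1142 lower) and 56.4% after cyclic loess (1521 and 1178). It was 87.7% after median centring (4390 and 615), which moved the median of all genes from -0.056 to 0.081, and 84.2% among males only (770 and 145). The total fell to 3183 without KO 2, 2904 without KO 3 and 2240 without KO 4. Higher genes numbered 1781 without KO 4. Lower genes numbered 2357 without WT 1, 908 without WT 3, 913 without WT 4, 936 without KO 1, 711 without KO 2, 742 without KO 3 and 459 without KO 4. Without WT 1, 187 genes were lower by at least 1 log2 unit.

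The KO arrays had a wider spread of values than the WT arrays. Their interquartile range was 2.45 to 2.65 log2 units (mean 2.56 ± 0.09, SD, n = 4), against 2.06 to 2.20 in WT (2.15 ± 0.06, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays allow). Genes with a mean level of 4 to 5 had a median change of 0.45 and those of 5 to 6 of 0.50, while genes under 2 had -0.19 and genes of 8 or more 0.08. The called list members given with values below were chosen as ones whose call held in each alternative that tested them but males only, so they are steadier than the other called members. Many gene groups below lie at middle levels, so each is also set against 10000 random lists of the same size matched on mean level, as a percentile of its median. Members of a list were not kept out of its random lists, and near the highest levels the draws repeat the gene of highest level. The random lists draw genes independently, while list members were correlated (estimated at 0.59 in the macrophage and 0.46 in the neutrophil list). Their spread is then too narrow, so an extreme percentile does not by itself show an effect of genotype. Neutrophil markers lay at percentile 99.99, yet their list level did not separate the genotypes (exact two-sided permutation p = 0.371). Of the 44 lists 19 lay above and 4 below the central 95% of their matched lists, and 16 of the 22 lists that camera called higher lay above it. The acinar enzymes are among those below, but their percentile cannot be read, for the reason given with that list. Camera with its preset correlation called 22 lists higher and 3 lower in KO. With an estimated correlation it called 0, the smallest adjusted p being 0.107. The rotation test fry called 22 lists whose genes moved, on balance, in one direction. Among them were histones and cholesterol synthesis, which camera did not call. Fry did not call actin and Hippo targets, extracellular matrix, NF-kB targets, secretory transport and fatty acid synthesis, which camera called. At an unadjusted exact permutation test of the list levels 23 lists reached the smallest p possible (0.0286), none of which passes after adjustment. This test and that of the interquartile range take the arrays as unpaired, and with replicate pairs neither could reach a p under 0.05.

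**Figure D2:**
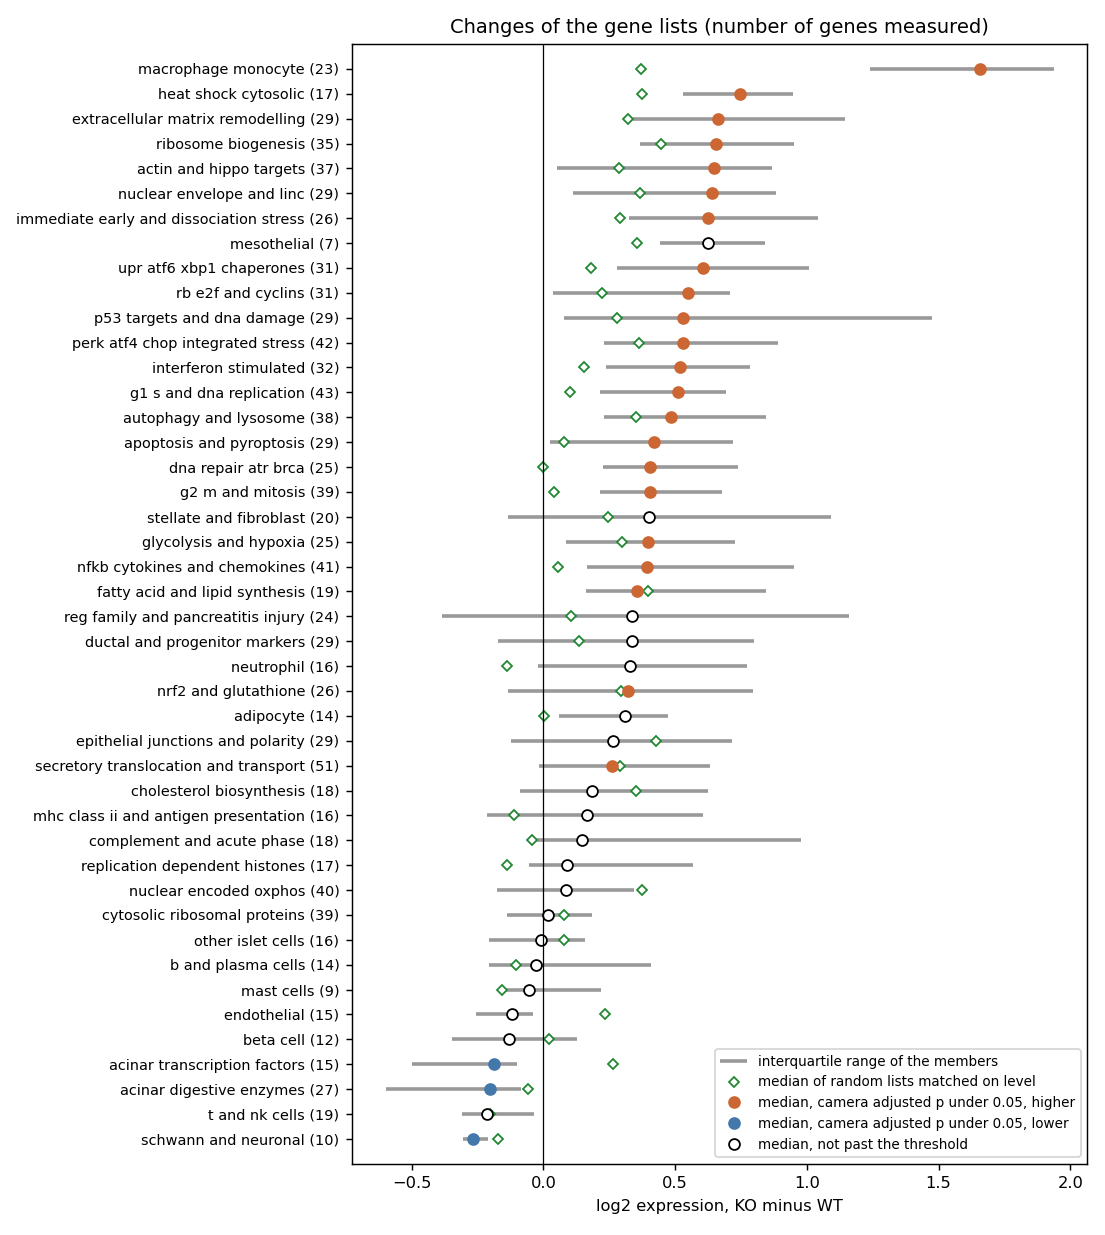
The median log2 change (KO minus WT, horizontal axis) of the measured members of each of the 44 gene lists (vertical axis, with the number measured), where grey bars are the interquartile range of the members and open diamonds the median expected of random lists matched on level. The macrophage and monocyte list had the median of 1.66 against a matched expectation of 0.37, and the acinar transcription factors had -0.19 against 0.26.

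**Figure D3:**
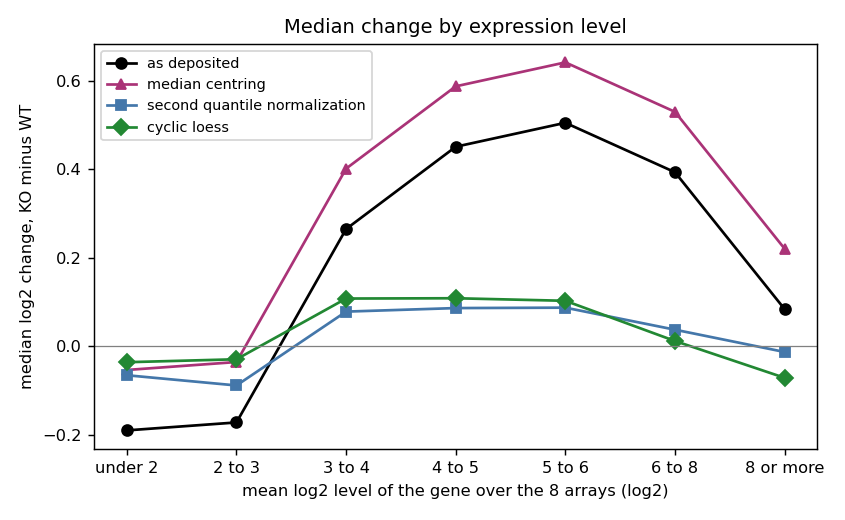
The median log2 change (KO minus WT, vertical axis) of genes binned by mean log2 level over the 8 arrays (horizontal axis), as deposited and after 3 other scalings. Genes of level 5 to 6 had 0.50 as deposited, 0.64 after median centring, 0.09 after a second quantile normalization and 0.10 after cyclic loess.

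Among acinar digestive enzymes, 0 of 27 measured genes rose and 10 fell (0 and 10 when adjusted over the list alone). The list median was -0.20 (camera adjusted p = 4.29e-05, adjusted p = 0.179 with an estimated correlation), at percentile 0.02 of the level-matched lists. Those matched lists hold the enzymes themselves, and their median (-0.06) is the change of the enzyme Ctrb1, so this percentile cannot be read. Besides Cela3a, Amy2b and Ctrc, trypsinogen Prss2 fell by 0.89 on the log2 scale (adjusted p = 0.0039). Of the 27 enzymes, 18 had a WT mean of at least 11 log2 units, close to the maximum of the arrays (at most 12.47). Their median change was -0.20, while that of the 9 others was -0.50. Amylases, elastases, trypsinogens and Reg3 proteins have near-identical copies whose transcripts could share probes, so values of single members are uncertain. In acinar transcription factors, 0 of 15 measured genes rose and 3 fell (0 and 4 when adjusted over the list alone). Its median change was -0.19 (camera adjusted p = 0.015, adjusted p = 0.347 with an estimated correlation), at percentile 0.58 of the level-matched lists. The call was lost without WT 1 (median -0.16). Bhlha15 (Mist1), which maintains the secretory state, had a change of -1.42 ± 0.12 (adjusted p = 0.00057), and Rbpjl, a subunit of the PTF1 complex, of -1.60 ± 0.17 (adjusted p = 0.00126). Ptf1a itself (0.03 ± 0.31, limma adjusted p = 0.957) and Nr5a2 (-0.26 ± 0.18, limma adjusted p = 0.307) did not pass.

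Among chaperones and other genes of the ATF6 and XBP1 arms of the unfolded protein response, 16 of 31 measured genes rose and 1 fell (21 and 1 when adjusted over the list alone). The median of these genes was 0.61 (camera adjusted p = 2.1e-07, adjusted p = 0.347 with an estimated correlation), at percentile 99.97 of the level-matched lists. The endoplasmic reticulum chaperone Hsp90b1 (1.77 ± 0.15), the disulfide isomerase Pdia3 (1.48 ± 0.14), Creld2 (1.68 ± 0.17) and the oxidase Ero1a (2.06 ± 0.21) rose. In the PERK, ATF4 and CHOP list, 16 of 42 measured genes rose and 0 fell (16 and 1 when adjusted over the list alone). As a list, the median was 0.53 (camera adjusted p = 3.15e-06, adjusted p = 0.423 with an estimated correlation), at percentile 95.67 of the level-matched lists. Besides Ddit3 and Fgf21, the pseudokinase Trib3 (2.27 ± 0.20) and the phosphatase subunit Ppp1r15a (1.57 ± 0.19) rose. In cytosolic heat shock genes, 8 of 17 measured genes rose and 1 fell (13 and 1 when adjusted over the list alone), with Hspa4l (1.68 ± 0.16) and Hspa4 (1.15 ± 0.19) higher and the small heat shock protein Cryab (-0.84 ± 0.13) lower. The members had a median of 0.75 (camera adjusted p = 4.29e-05, adjusted p = 0.303 with an estimated correlation), at percentile 99.06 of the level-matched lists. Among genes of secretory translocation and transport, 15 of 51 measured genes rose and 3 fell (15 and 4 when adjusted over the list alone), with Arf4 (1.38 ± 0.17), Stt3a (1.18 ± 0.16) and Kdelr2 (1.46 ± 0.21) among the higher ones. Over the list, the median was 0.26 (camera adjusted p = 0.000557, adjusted p = 0.594 with an estimated correlation), at percentile 39.06 of the level-matched lists. The call was lost after a second quantile normalization and the median turned in direction after cyclic loess (-0.0269). The list level of KO 2 (-0.0087) lay below that of WT 3 (0.0060), while the other KO arrays lay above all WT arrays (exact two-sided permutation p = 0.0571).

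Among p53 targets and DNA damage genes, 13 of 29 measured genes rose and 0 fell (15 and 2 when adjusted over the list alone). The list median was 0.53 (camera adjusted p = 1.14e-05, adjusted p = 0.179 with an estimated correlation), at percentile 97.99 of the level-matched lists. Besides Cdkn1a, the death receptor Tnfrsf10b (1.07 ± 0.12), the receptor Eda2r (2.19 ± 0.26) and cyclin G Ccng1 (1.59 ± 0.20) rose. In the DNA repair list, 6 of 25 measured genes rose and 0 fell (8 and 0 when adjusted over the list alone), with Rad50 (1.04 ± 0.12), Msh6 (1.08 ± 0.15) and Atr (1.49 ± 0.23) among them. Its median change was 0.41 (camera adjusted p = 0.000118, adjusted p = 0.107 with an estimated correlation), at percentile 99.9 of the level-matched lists. Of the genes of the G1/S transition and DNA replication, 16 of 43 measured genes rose and 0 fell (27 and 0 when adjusted over the list alone). The median of these genes was 0.51 (camera adjusted p = 1.41e-07, adjusted p = 0.302 with an estimated correlation), at percentile 100 of the level-matched lists. The sliding clamp Pcna (1.28 ± 0.15), primase Prim1 (1.30 ± 0.22) and Rpa2 (0.77 ± 0.15) rose. In the G2/M list, 9 of 39 measured genes rose and 0 fell (9 and 0 when adjusted over the list alone), with topoisomerase Top2a (1.02 ± 0.22) the one of smallest p. As a list, the median was 0.40 (camera adjusted p = 4.29e-05, adjusted p = 0.423 with an estimated correlation), at percentile 99.99 of the level-matched lists. The list of RB, E2F and cyclins included Cdkn1a, which blocks the cell cycle. In it 15 of 31 measured genes rose and 2 fell (17 and 3 when adjusted over the list alone), with Rbl1 (1.01 ± 0.21) and cyclin Ccnd2 (0.91 ± 0.19) among the higher ones. The members had a median of 0.55 (camera adjusted p = 0.000757, adjusted p = 0.179 with an estimated correlation), at percentile 99.54 of the level-matched lists. For replication-dependent histones, 4 of 17 measured genes rose and 0 fell (4 and 0 when adjusted over the list alone) (median 0.09, camera adjusted p = 0.17, percentile 99.85 of matched lists). That list passed as higher after a second quantile normalization (0.22), after cyclic loess (0.24) and by the rotation test fry (adjusted p = 0.0303), and not with an estimated correlation (adjusted p = 0.347). H4c9 rose by 0.80 ± 0.16.

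In nuclear envelope and LINC complex genes, the partners of the lamina, 14 of 29 measured genes rose and 1 fell (14 and 2 when adjusted over the list alone). The inner membrane proteins Tmem43 (1.68 ± 0.20), Tor1aip1 (0.92 ± 0.15) and Ankle2 (1.48 ± 0.25) rose. Over the list, the median was 0.64 (camera adjusted p = 0.000118, adjusted p = 0.179 with an estimated correlation), at percentile 98.74 of the level-matched lists. Among actin and Hippo pathway targets, 10 of 37 measured genes rose and 0 fell (13 and 0 when adjusted over the list alone), led by gamma actin Actg1 (1.74 ± 0.17). The list median was 0.65 (camera adjusted p = 0.000396, adjusted p = 0.486 with an estimated correlation), at percentile 99.93 of the level-matched lists. The list level of KO 1 (-0.16) lay below that of WT 2 (0.08), while KO 2 to KO 4 lay above all WT arrays (exact two-sided permutation p = 0.0571). For ribosome biogenesis, 22 of 35 measured genes rose and 0 fell (24 and 0 when adjusted over the list alone), including Nop14 (1.11 ± 0.14), Mybbp1a (1.04 ± 0.17) and Ncl (0.91 ± 0.17). Its median change was 0.65 (camera adjusted p = 6.3e-08, adjusted p = 0.347 with an estimated correlation), at percentile 97.8 of the level-matched lists. By contrast, of the ribosomal proteins themselves 1 of 39 measured genes rose and 2 fell (1 and 2 when adjusted over the list alone) (median 0.02, camera adjusted p = 0.961, percentile 26.16 of matched lists). Cyclic loess turned that median to -0.18, and the list then passed as lower. It also passed among genes above the median level (0.016 against 0.32 of all genes there). Of the nuclear-encoded genes of oxidative phosphorylation 2 of 40 measured genes rose and 1 fell (1 and 0 when adjusted over the list alone) (median 0.09, camera adjusted p = 0.588, percentile 0.25 of matched lists). Cytochrome c, encoded by Cycs, rose by 0.95 ± 0.15. After a second quantile normalization and after cyclic loess the median of this list turned to -0.26 and the list passed as lower.

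Macrophage and monocyte markers had the largest median of the 44 lists. Of these markers 12 of 23 measured genes rose and 0 fell (21 and 0 when adjusted over the list alone). The median of these genes was 1.66 (camera adjusted p = 1.41e-07, adjusted p = 0.347 with an estimated correlation), at percentile 100 of the level-matched lists. Besides Adgre1, the Fc receptor Fcgr1 (1.92 ± 0.27), the chemokine receptor Ccr2 (1.66 ± 0.29) and Plac8 (1.5 ± 0.31) rose. The list level per array was -1.34, -0.11, -1.04 and -0.55 in WT 1 to WT 4 and -0.17, 1.25, 0.75 and 1.21 in KO 1 to KO 4, so KO 1 lay below WT 2 (exact two-sided permutation p = 0.0571). Within the replicate pairs 1 to 4, KO minus WT was 1.17, 1.36, 1.79 and 1.76, and with the replicate number as a block 20 of the 23 genes rose. Among interferon-stimulated genes, 15 of 32 measured genes rose and 0 fell (18 and 0 when adjusted over the list alone), such as Ifih1 (1.31 ± 0.21), Ifit1 (1.06 ± 0.20) and Isg15 (0.73 ± 0.14). As a list, the median was 0.52 (camera adjusted p = 4.97e-06, adjusted p = 0.179 with an estimated correlation), at percentile 99.86 of the level-matched lists. In NF-kB targets, cytokines and chemokines, 2 of 41 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone). The members had a median of 0.39 (camera adjusted p = 0.0139, adjusted p = 0.67 with an estimated correlation), at percentile 99.93 of the level-matched lists. The call was lost without WT 1 (0.38), without KO 2 (0.34) and without KO 4 (0.27). The list levels of KO 1 (-0.30) and KO 3 (-0.27) lay below those of WT 2 (0.07) and WT 4 (-0.17). KO 2 and KO 4 lay above all WT arrays (exact two-sided permutation p = 0.229). In the extracellular matrix list, 5 of 29 measured genes rose and 0 fell (8 and 0 when adjusted over the list alone), such as the membrane protease Mmp14 (1.66 ± 0.34). Over the list, the median was 0.66 (camera adjusted p = 0.000481, adjusted p = 0.538 with an estimated correlation), at percentile 99.5 of the level-matched lists. The list level of KO 1 (-0.38) lay below those of WT 2 (-0.06), WT 3 (-0.28) and WT 4 (-0.32), while KO 2 to KO 4 lay above all WT arrays. The genotypes thus overlapped (exact two-sided permutation p = 0.114). Of stellate cell and fibroblast markers 2 of 20 measured genes rose and 0 fell (2 and 0 when adjusted over the list alone), and the list did not pass (median 0.40, camera adjusted p = 0.119, percentile 85.39 of matched lists). It passed with the replicate number as a block (camera adjusted p = 0.00801), without WT 3 (0.50) and without KO 1 (0.56). With an estimated correlation it did not pass (adjusted p = 0.67, or 0.232 with the block). Periostin (Postn), a matrix protein, rose by 1.72 ± 0.24.

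**Figure D4:**
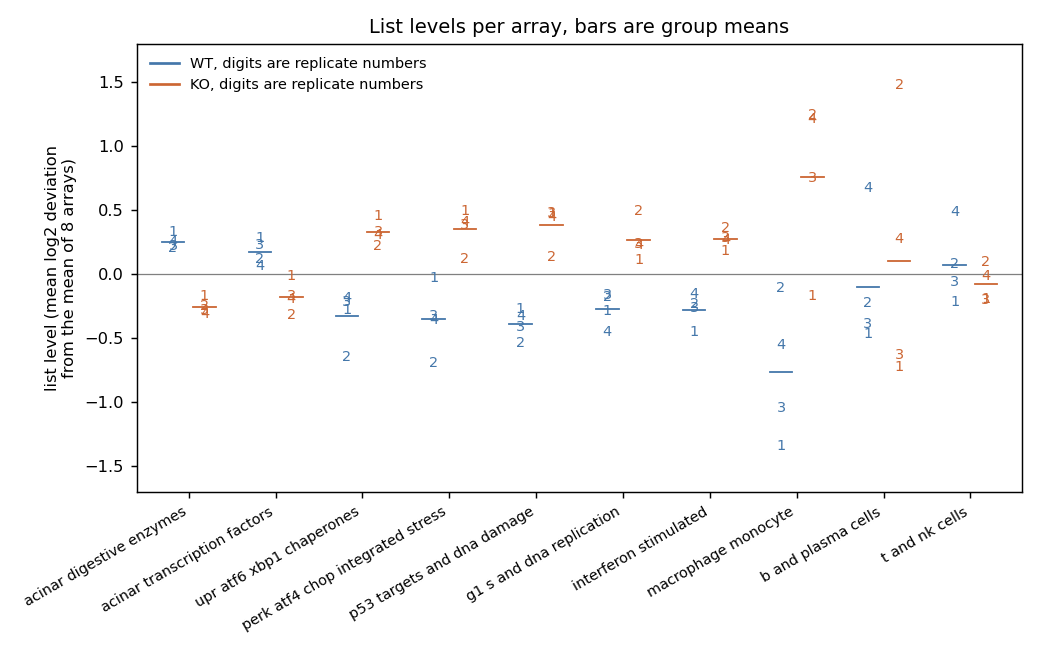
The list level (vertical axis, mean log2 deviation of the members from their mean over the 8 arrays) of 10 gene lists (horizontal axis), where each digit is 1 array shown by its replicate number and bars are the means of 4 arrays. The acinar enzyme list separates the genotypes with group means of 0.25 (WT) and -0.25 (KO), whereas KO 1 of the macrophage and monocyte list (-0.17) lies below WT 2 (-0.11).

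Markers of most other cell types gave no list call. Median levels were 2.32 for neutrophil, 2.08 for T and NK, 2.58 for B and plasma and 1.87 for mast cell markers. These lie near or below the medians of the arrays (2.13 to 2.33), where a change could be hidden, so a missing call does not show that these cells were unchanged. Of neutrophil markers, 1 of 16 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone) (median 0.33, camera adjusted p = 0.41, percentile 99.99 of matched lists). Of T and NK cell markers, 0 of 19 measured genes rose and 2 fell (0 and 2 when adjusted over the list alone) (median -0.21, camera adjusted p = 0.145, percentile 45.87 of matched lists), and that list passed without WT 1 (-0.25). Of B and plasma cell markers, 0 of 14 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone) (median -0.03, camera adjusted p = 0.961, percentile 72.94 of matched lists). Of mast cell markers, 0 of 9 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone) (median -0.06, camera adjusted p = 0.707, percentile 87.13 of matched lists). Of endothelial markers, 0 of 15 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone) (median -0.12, camera adjusted p = 0.204, percentile 1.56 of matched lists). That list passed as lower after a second quantile normalization (-0.45), after cyclic loess (-0.43), among genes above the median level (-0.16) and without KO 2 (-0.26). Of adipocyte markers, 1 of 14 measured genes rose and 1 fell (1 and 1 when adjusted over the list alone) (median 0.31, camera adjusted p = 0.585, percentile 96.64 of matched lists). Of mesothelial markers, 0 of 7 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone) (median 0.62, camera adjusted p = 0.205, percentile 86.85 of matched lists). Of beta cell markers, 0 of 12 measured genes rose and 2 fell (0 and 2 when adjusted over the list alone) (median -0.13, camera adjusted p = 0.204, percentile 17 of matched lists). That list passed among genes above the median level, where its median turned to 0.10 against 0.32 of all genes, and the oxidase Ero1b changed by -0.77 ± 0.13. The WT mean of Ero1b was 9.88, against 3.37 for Ins2 and 4.91 for Iapp of the same list, so its change cannot be assigned to beta cells. Of markers of other islet cells, 0 of 16 measured genes rose and 1 fell (0 and 1 when adjusted over the list alone) (median -0.01, camera adjusted p = 0.443, percentile 26.51 of matched lists), and the transcription factor Neurod1 changed by -0.73 ± 0.17. Of Schwann cell and neuronal markers 0 of 10 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone), yet the list passed. The list median was -0.27 (camera adjusted p = 0.0331, adjusted p = 0.261 with an estimated correlation), at percentile 11.47 of the level-matched lists. That call was lost without WT 2 (-0.21) and after each of the 3 other scalings (-0.10 to -0.15).

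Ductal and progenitor markers split, in that 5 of 29 measured genes rose and 3 fell (7 and 4 when adjusted over the list alone) (median 0.34, camera adjusted p = 0.17, percentile 93.24 of matched lists). Keratin 19 (Krt19) rose by 1.13 ± 0.15, while the mucin Muc1 changed by -1.10 ± 0.18 and the trefoil peptide Tff1 by -0.91 ± 0.19. The list passed without KO 2 (0.30). The list of Reg proteins and pancreatitis genes also split, in that 7 of 24 measured genes rose and 2 fell (11 and 6 when adjusted over the list alone) (median 0.34, camera adjusted p = 0.17, percentile 96.21 of matched lists). The early response factor Egr1 (1.67 ± 0.21) was higher and the lectin Reg3d (-1.08 ± 0.19) lower. Of epithelial junction genes, 5 of 29 measured genes rose and 3 fell (6 and 3 when adjusted over the list alone) (median 0.27, camera adjusted p = 0.0787, percentile 9.21 of matched lists). Connexin Gjb1 (-1.02 ± 0.16) was lower and alpha-catenin Ctnna1 (0.94 ± 0.20) higher. The list passed with the replicate block (camera adjusted p = 0.0436), without WT 1 (0.30) and without KO 2 (0.27). With an estimated correlation it did not pass (adjusted p = 0.639, or 0.236 with the block). Immediate early genes, which also respond to tissue handling, were called higher as a list. Among these, 9 of 26 measured genes rose and 0 fell (11 and 1 when adjusted over the list alone), such as Egr1 (1.67 ± 0.21), Atf3 (2.06 ± 0.31) and Ier3 (1.46 ± 0.24). Its median change was 0.62 (camera adjusted p = 0.000149, adjusted p = 0.347 with an estimated correlation), at percentile 99.33 of the level-matched lists. For apoptosis and pyroptosis, 8 of 29 measured genes rose and 0 fell (8 and 0 when adjusted over the list alone), with the initiator caspase Casp8 (1.55 ± 0.31) among them. The median of these genes was 0.42 (camera adjusted p = 0.00509, adjusted p = 0.347 with an estimated correlation), at percentile 99.48 of the level-matched lists. Of class II antigen presentation genes, 0 of 16 measured genes rose and 0 fell (0 and 0 when adjusted over the list alone) (median 0.17, camera adjusted p = 0.671, percentile 98.48 of matched lists). Their median level of 2.28 lay near the medians of the arrays, where a change could be hidden. Of complement and acute phase genes, 1 of 18 measured genes rose and 1 fell (1 and 1 when adjusted over the list alone) (median 0.14, camera adjusted p = 0.464, percentile 94.96 of matched lists).

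Several lysosomal and metabolic lists were called higher. Among autophagy and lysosome genes, 16 of 38 measured genes rose and 0 fell (20 and 0 when adjusted over the list alone), including the cholesterol transporter Npc1 (1.86 ± 0.15), cathepsin Ctsh (1.53 ± 0.24) and the autophagy receptor Sqstm1 (1.11 ± 0.21). As a list, the median was 0.49 (camera adjusted p = 2.59e-06, adjusted p = 0.107 with an estimated correlation), at percentile 90.55 of the level-matched lists. In the NRF2 and glutathione list, 6 of 26 measured genes rose and 1 fell (6 and 1 when adjusted over the list alone), with Ugdh (1.62 ± 0.15), Ephx1 (2.14 ± 0.23) and Hmox1 (2.18 ± 0.40) higher. The members had a median of 0.32 (camera adjusted p = 0.0341, adjusted p = 0.303 with an estimated correlation), at percentile 57.2 of the level-matched lists. The call was lost without WT 2 (0.24), without KO 4 (0.31), among males only (0.31) and after each of the 3 other scalings (0.05 to 0.46). For glycolysis and hypoxia, 4 of 25 measured genes rose and 1 fell (4 and 1 when adjusted over the list alone), such as Pgk1 (1.03 ± 0.13) and Pfkfb3 (1.12 ± 0.17). Over the list, the median was 0.40 (camera adjusted p = 0.00432, adjusted p = 0.375 with an estimated correlation), at percentile 79.48 of the level-matched lists. The call was lost after a second quantile normalization (0.11) and cyclic loess (0.14). In fatty acid and lipid synthesis, 6 of 19 measured genes rose and 1 fell (6 and 1 when adjusted over the list alone), such as Elovl6 (1.26 ± 0.25) and Acsl5 (1.12 ± 0.23). The list median was 0.35 (camera adjusted p = 0.0443, adjusted p = 0.646 with an estimated correlation), at percentile 38.8 of the level-matched lists. The call was lost without KO 2 (0.12), WT 1 (0.53), WT 2 (0.43) or WT 4 (0.34), with sex as a term (0.35), with array weights (0.24) and after each of the 3 other scalings (0.21 to 0.49). The list level stood apart in KO 2 (1.09 against -0.026 to 0.029 in the other KO arrays), where that of adipocyte markers was also high (1.78 against -0.59 to -0.026). Of cholesterol synthesis genes, 5 of 18 measured genes rose and 1 fell (5 and 1 when adjusted over the list alone) (median 0.18, camera adjusted p = 0.0759, percentile 12.48 of matched lists). The list passed without KO 3 (0.28). Among its genes Cyp51 (1.49 ± 0.20) and Ebp (1.02 ± 0.15) were higher and Insig1 (-1.14 ± 0.16) lower.

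Among the 3467 genes with a mean level of at least 5, whose median change was 0.44, camera called 4 of the 33 lists with at least 2 members there, namely acinar enzymes, acinar transcription factors, Reg and injury genes (median -0.082, against 0.34 over all measured members) and ribosomal proteins. Of the 25 lists called over all genes, 2 kept their call there, 19 lost it and 4 (G1/S, G2/M, DNA repair and Schwann cell) had too few members to be tested. Several medians of lost calls stayed high, as in the macrophage (1.62), immediate early (0.99), actin and Hippo (0.89), p53 (0.88), chaperone (0.67) and PERK (0.51) lists. Camera sets a list against the other genes tested, so these losses do not show that the lists did not change. The median of the interferon-stimulated list was -0.0040 there. Among genes above the median level (median change 0.32), calls were lost for the lists of PERK, G2/M, RB and E2F, nuclear envelope, actin and Hippo, extracellular matrix, autophagy, apoptosis, heat shock, NF-kB, secretory transport, NRF2, glycolysis and fatty acid synthesis, and the Schwann cell list was not tested.

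With the replicate number as a block, the number of higher genes grew by over 1.5 times in some lists. It went from 2 to 8 in stellate and fibroblast markers, from 5 to 11 in extracellular matrix, from 10 to 18 in actin and Hippo targets, from 2 to 7 in NF-kB targets and from 9 to 14 in immediate early genes. It also went from 5 to 8 in ductal markers, from 4 to 7 in glycolysis, from 2 to 5 in oxidative phosphorylation, from 1 to 4 in complement, from 0 to 4 in class II presentation and from 0 to 1 in mesothelial markers. Lower genes went from 2 to 0 in RB, E2F and cyclins, from 0 to 2 in the PERK list, from 2 to 1 in beta cell markers, from 1 to 0 in adipocyte markers, glycolysis and the NRF2 list, and from 0 to 1 in p53 targets and immediate early genes.

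The comparison of the genotype effect between the sexes rests on 1 female per genotype, assumed to vary like the males. Glycam1, a mucin of lymph node vessels, passed the threshold among 22180 genes, with a difference (female KO minus female WT, less the same in males) of -5.47 ± 0.33 (limma adjusted p = 0.00716). It read 7.19 in WT 4, the WT female, and 1.75 to 2.22 in the other 7 arrays, so the call reflects 1 array and does not show that the sexes differ. The next genes by p were Cd209e (1.88 ± 0.33), Cd3e (-2.02 ± 0.36), Ccl12 (2.13 ± 0.38) and Bloc1s2 (1.73 ± 0.32), which did not pass (limma adjusted p = 0.9999 for each). At an unadjusted p under 0.05 there were 385 genes (1.74% of those tested), and among genes with a mean of at least 5 there were 0 past the threshold.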

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

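The tests on all leukocyte lists together, on a single KO animal as the whole of the macrophage difference, on its replicate pairs and on a lower share of acinar cells were chosen only after the result was seen. Arrays far from the other 3 of their group were looked for among 480 groups of 4 values and found in 31, where chance gives about 1 in 20 groups. Values are log2 levels, set against the range of the other 3 arrays of the group. KO 1 stood apart in Amy2b (7.99 against 7.60 to 7.66) and Cxcl16 (4.17 against 5.21 to 5.34). KO 2 lay away from its group in Scd1 (9.28 against 6.47 to 6.78), Pax5 (3.36 against 2.14 to 2.19) and Agpat2 (5.22 against 4.38 to 4.41). KO 3 was set apart from the rest of its group for Ly6g (1.77 against 1.87 to 1.88) and Tmem43 (5.43 against 4.59 to 4.69). KO 4 stood apart in Atr (4.60 against 4.12 to 4.15), Hspb1 (4.96 against 4.79 to 4.81) and Cd209e (3.27 against 1.42 to 1.64). WT 1 lay away from its group in Acot2 (6.01 against 4.76 to 4.91), Cela3a (6.39 against 6.71 to 6.75), Lmnb2 (2.20 against 2.69 to 2.78), Zap70 (2.54 against 3.51 to 3.53) and Serping1 (5.0 against 6.26 to 6.43). WT 2 was set apart from the rest of its group for Fcgr1 (3.32 against 2.25 to 2.36), Ccng1 (7.14 against 7.72 to 7.75), Arf4 (7.24 against 7.80 to 7.88) and Hmox1 (5.11 against 3.22 to 3.51). WT 3 stood apart in Msh6 (2.54 against 2.72 to 2.75). WT 4 lay away from its group in Jchain (3.50 against 1.94 to 2.13), Btg2 (4.50 against 5.53 to 5.69), Atp6v1a (4.29 against 4.52 to 4.54), Glycam1 (7.19 against 1.83 to 1.98) and Cd3e (4.21 against 1.84 to 2.19). Among list levels, the arrays apart from their group were those of ductal and progenitor markers in WT 3 (-0.0119 against -0.209 to -0.18), p53 targets and DNA damage genes in KO 2 (0.138 against 0.445 to 0.48), Reg and pancreatitis genes in KO 4 (0.517 against 0.0663 to 0.131), fatty acid and lipid synthesis in KO 2 (1.09 against -0.0264 to 0.0292), autophagy and lysosome in KO 1 (0.153 against 0.297 to 0.319) and glycolysis and hypoxia in WT 1 (-0.266 against -0.201 to -0.197).

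The test of the genotype effect between the sexes passed for Glycam1 (difference -5.47, limma adjusted p = 0.00716). It rests on the 7.19 of WT 4, the WT female, against 1.75 to 2.22 in the other 7 arrays, so it shows 1 array apart and no difference between the sexes can be read from it. In rows left out of the gene tests, 834 of 16010 rows with no symbol were higher in KO and 825 lower (limma, Benjamini-Hochberg), and of 1814 rows with several symbols 126 were higher and 87 lower.

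The count of 4792 genes was set against other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the real one, and the highest other split gave 0. A share of 1 in 35 is under the 0.05 set beforehand, but only if the arrays are taken as unpaired. The replicate numbers were taken above to pair them. The 8 splits that part all 4 replicate pairs are too few for a share under 0.05, so chance cannot be excluded for paired arrays. The highest other of them gave 0.

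Genes of middle level were higher in KO, with a median of 0.47 at mean levels of 4 to 6. The WT 2 array alone is argued against, since without it the median was 0.39. A second quantile normalization lowered the median to 0.0864, under the 0.1 that the wider spread of values on the KO arrays would leave, so normalization may account for much of it; because that step forces the same distribution on every array, it would also remove a real broad rise. A state that varies between animals of 1 genotype, such as RNA quality, cannot be told apart: across genes, WT 2 minus WT 1 correlated at -0.279 with KO minus WT 3 and WT 4, short of the -0.3 set beforehand, and no quality values are at hand. The biological alternative, a broad change of transcripts after Lmna loss, stays open and untested.

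Macrophage and monocyte markers were higher in KO (median 1.66), and the level-dependent rise is argued against, as the median lay at percentile 100 of the level-matched lists, whose median was 0.37. Those lists draw genes independently while these markers were correlated (0.59), so the percentile overstates how far the list stands apart. A single KO animal as the whole difference is argued against by tests added later, with a list level difference of at least 1.33 (1.52 in full) whichever array was left out and differences of 1.17, 1.36, 1.79 and 1.76 within replicate pairs 1 to 4. The condition set beforehand for a single KO animal was met, as the lowest KO array (KO 1) minus the highest WT array (WT 2) gave -0.0628, but this shows only an overlap, since KO 2 to KO 4 (1.25, 0.75 and 1.21) lay above all WT arrays. More leukocytes of all kinds cannot be told apart: the median lay 1.68 above the higher of the T and NK and the B and plasma cell medians, but those lists have median levels of 2.08 and 2.58, near the medians of the arrays (2.13 to 2.33), where a rise could be hidden. An effect of genotype on macrophages in the tissue is a hypothesis that remains beside it and beside unequal animals, and the call did not hold with an estimated correlation (adjusted p = 0.347).

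Digestive enzymes were lower in KO as a list (median -0.20), with 10 of 27 measured genes past the threshold. The camera call did not hold with an estimated correlation (adjusted p = 0.179). The level-dependent trend cannot be judged. The median lay at percentile 0.02 of matched lists, but these hold the enzymes themselves, and their own median (-0.06) is the change of the enzyme Ctrb1. A lower share of acinar cells, with nothing else changed, would raise the markers of every other cell type alike. The medians of 5 non-acinar lists spanned 1.79 log2 units, from -0.13 in beta cell to 1.66 in macrophage markers. Most of that span came from the macrophage list. The endothelial (-0.12), other islet (-0.01) and stellate (0.40) medians lay closer to that of beta cells, so this test cannot exclude a lower share. The beta cell median is itself uncertain. In that list Mafa (-0.77 ± 0.23) and Ero1b (-0.77 ± 0.13) were lower, but Ero1b cannot be assigned to beta cells. Ins2 (0.10 ± 0.39) and Iapp (0.19 ± 0.42) were not lower. Probes shared between near-identical enzyme genes were not tested and stay open. Beside them stands, as a hypothesis found and tested on the same data, a fall of enzyme transcripts within acinar cells after Lmna loss.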

How the results depend on the processing

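Cyclic loess, the level-matched lists and the block together with an estimated correlation were chosen after seeing the data. With sex as a term, the replicate number as a block, a trend with robust eBayes, array weights or the mean of a gene's rows, all 5 gene counts stayed within 1.5 times their values. With the replicate block they were 5046 in all, 3698 higher and 1348 lower, and the block changed the calls of 2 of the 44 lists, stellate and fibroblast markers and epithelial junctions. Males only, with fewer arrays, gave 915 genes (770 higher, 145 lower, 504 and 67 by at least 1 log2 unit). A second quantile normalization gave 2370 (1228 higher, 379 and 267 by at least 1), of which 1842 were among the 4792, and cyclic loess 2699 (1521 higher, 396 and 266 by at least 1), with 2072 shared. Median centring gave 615 lower, and 1641 higher and 70 lower by at least 1. With a mean level of at least 5, and so fewer genes, there were 1620 (1430 higher, 190 lower, 428 and 50 by at least 1), 4 lists called and 0 genes for the sex difference. Among genes above the median level there were 647 lower genes and 13 lists. All rows of the table gave 350 lower by at least 1. The ordinary equal-variance test gave 2381 (1534 higher, 847 lower, 647 and 70 by at least 1). Without each array in turn, the counts ranged from 2240 to 6070 in all, 1781 to 3713 higher, 459 to 2357 lower, 776 to 1367 higher by at least 1 and 91 to 187 lower by at least 1. Fewer arrays lower such counts, yet the total rose to 6070 without WT 1. Across rows, WT 1 correlated about as well with the KO arrays (mean 0.937) as with the other WT arrays (mean 0.938). Its closest array was KO 1 (0.951), while that of each other WT array was a WT array. Whether this made the count rise was not tested. In all 8 of these fits 2084 genes kept their call, under all 3 other scalings 1595 did, and 1340 (997 higher, 343 lower) did in both. Lmna stayed between -0.33 and -0.13 without each array and was not called in any of the settings run. List calls numbered 22 to 26 without each array and 0 with an estimated correlation, also 0 with it and the replicate block together. Lists at the smallest exact p numbered 18 to 23 without each array. Medians turned in direction for oxidative phosphorylation after a second quantile normalization (-0.26) and cyclic loess (-0.26), for ribosomal proteins (-0.18) and secretory transport (-0.0269) after cyclic loess, for Reg and injury genes (-0.0822) and interferon-stimulated genes (-0.0040) at a mean of at least 5, and for beta cell markers among genes above the median level (0.10). Of the 144 genes called among those the naming rule took, 65 lost their call among males only, 38 after a second quantile normalization and 30 after cyclic loess. Of those given with values in the results, Scd1 lost its call in the settings given with it. Among males only Fetub (3.39), Adgre1 (2.19), Serpini2 (-2.43), Lmnb1 and Rb1 lost theirs, as did Tff1, Ero1b, Neurod1, Mmp14, Ccr2, Plac8, Top2a, Rbl1, Ccnd2, Tor1aip1, Ankle2, Ifit1, Hmox1, Ncl, Elovl6, Acsl5, Ctnna1, Casp8 and H4c9. In each of these results the cause was not tested. No background values are at hand, so it is not known how far dim rows such as Lmna lie above background.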

Other observations

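Lymphoid transcripts stood out in single arrays. In WT 4, where Glycam1 read 7.19, the T cell gene Cd3e read 4.21 (1.84 to 2.49 in the other 7 arrays) and the complement receptor Cr2 3.19 (1.26 to 2.35). The B cell gene Ms4a1 read 4.61 in KO 2, 3.50 in WT 4 and 2.38 in KO 4, and the plasma cell gene Jchain 7.29 in KO 2 and 5.27 in KO 4. Jchain read 2.40 and 2.83 in KO 1 and KO 3 and 2.13, 2.11, 1.94 and 3.50 in WT 1 to WT 4, so it was higher in KO within each replicate pair, and its difference did not pass (2.03 ± 0.94, limma adjusted p = 0.138). The list level of B and plasma cells was 1.48 in KO 2 and 0.67 in WT 4, and that of adipocyte markers 1.78 in KO 2. Cd3e, Cr2, Ms4a1 and Jchain were looked at after their values were seen.

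Dhrs9, a short-chain dehydrogenase, had the smallest p of all 22180 genes and lies outside the rule for named genes, so it was chosen after its values were seen. It read 1.84 to 1.93 in the WT arrays and 5.44 to 5.93 in the KO arrays, a difference of 3.84 ± 0.13 (limma adjusted p = 9.83e-07). Its WT values lie below the medians of the arrays (2.13 to 2.33) and background is unknown, so the size of this difference is uncertain. The Y-linked gene Eif2s3y, also chosen after its values were seen, read 4.80 to 5.57 in the WT males and 6.78 to 7.37 in the KO males, next to 1.85 and 1.23 in the females. The Y-linked genes Uty and Kdm5d were higher in the KO males too. Uty read 3.11 to 4.56 in WT and 4.74 to 5.13 in KO males, and Kdm5d 2.33 to 3.31 and 3.48 to 3.89. The cause was not tested.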
